A study of Homo sapiens with 6 samples.

How the data were processed

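Total RNA was extracted from HEK cells, treated with DNase, depleted of ribosomal RNA and made into stranded libraries, per the labels' protocols. The groups came from the sample labels: 3 libraries of a NOPCHAP1 knockout clone and 3 of a control clone. The authors deposited 1 table of raw read counts per gene for the 6 libraries, with 28278 rows. Each row has a symbol, and most have a gene number. The submitters' processing notes name TopHat2, featureCounts and the hg38 build. Their versions, the annotation, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. Counts of overlapping or antisense genes and of near-identical copies, such as U3, snRNA and 7SL genes, are therefore uncertain. All 6 count columns were matched to samples by name. There were 7173 rows without a read in any library and 99 rows without a gene number. Gene numbers were matched to an NCBI gene table for 28120 rows, and 26941 rows were matched to GENCODE v29, whose GRCh38 coordinates are printed. Mitochondrial mRNAs were not analysed here.

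The deposited counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total count of 15, which left 14724 genes, and libraries were scaled with TMM factors, from 0.886 in KO 1 to 1.10 in KO 2. The quasi-likelihood F-test compared KO with control, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The common biological coefficient of variation was 13.9%. CPM values use the TMM-scaled library sizes, and log2-CPM values a prior count of 2. Total counts were 23953714 to 38991065 reads per library. For genes with few reads, a ratio of pooled rates is given with an exact 95% interval, which covers counting error only. Differences of per-library levels were tested with exact two-sided permutation tests, whose smallest p for 3 against 3 is 0.1.

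Gene lists were fixed before the data were examined: 42 lists, of which 39 had at least 3 tested members. Each was tested with camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Members were counted over all genes and adjusted over the list alone. Host genes of snoRNAs were found as GENCODE v29 genes on the same strand that contain the snoRNA. Replicates of a group differed by far more than sampling noise, with a chi-square per degree of freedom of 23.7 to 87.6 between pairs of libraries, so no library was a copy of another.

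The genes named in the text were set by a rule written before the data were examined. It names NOPCHAP1, every tested core protein and assembly factor of box C/D particles, and up to 12 genes in each direction with the largest change among those past the threshold, with a mean of at least 2 CPM, groups that do not overlap and a gene symbol that is not a clone, locus or pseudogene name. It also names up to 4 members of each list past the threshold or, where there were none, up to 2 with the smallest p, and the 6 SNORD and 3 SNORA genes with the highest mean CPM. Genes named outside the rule are said to be, and 3 genes that the rule names are not reported here.

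The procedure was tested on simulated counts for the comparison of KO with control, with 200 changed genes drawn from the real means and library sizes. Among changed genes that were tested, 35.8% of those changed 1.5-fold, 70.8% of those changed 2-fold and 98.4% of those changed 4-fold were called, and 6 of 136 calls were false, over 14576 genes tested. With no change simulated there were 2 calls. A simulated fall of all box C/D snoRNAs by 1.2-fold gave a median of -0.26 and a camera adjusted p of 2.87e-11, with 0 single snoRNAs called, over 14556 genes tested. A fall of 1.5-fold gave 0 calls among 141 and a fall of 2-fold 57 among 138. The simulated libraries varied gene by gene and lacked the library-wide trends of the real ones.

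Alternatives set before the data were examined were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, no low-count filter, a stricter one of 1 CPM in 3 libraries, library sizes without small RNA, rRNA and mitochondrial genes, the replicate number as a block, each library left out in turn, a glmTreat test against a log2 fold change of 1, an adjusted p under 0.01, and other summaries, prior counts and definitions of the snoRNA classes. Alternatives chosen after seeing the data were 1 surrogate variable (sva 3.50.0), a spline trend of each library on GC content and transcript length as an offset, fitted on the 14173 tested genes (96.3%) that have both, the comparison without KO 1 and control 3, summed snoRNA counts without SNORD3A, and DESeq2 on the genes that pass the edgeR filter. Plots were drawn with matplotlib 3.10.9.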

Results

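RNA was measured in HEK cells, a human embryonic kidney line, in 6 libraries. There were 3 libraries from a clone labelled as a knockout of NOPCHAP1 (KO 1 to KO 3) and 3 from a control clone (control 1 to control 3). Each group was 1 clone, so the clone and the knockout cannot be separated in any comparison below, and the labels do not tell whether the replicates were separate cultures. All p-values therefore measure the spread between these samples, which may be technical. The libraries were total RNA depleted of ribosomal RNA, and held 23953714, 36730351 and 38135723 counted reads in KO 1, KO 2 and KO 3 and 34750117, 32300138 and 38991065 in control 1, control 2 and control 3. Mitochondrial rRNA took 22.6% to 25.9% of the counts and the 7SL RNA rows 7.75% to 11.9%. Box C/D small nucleolar RNAs (snoRNAs), which guide methylation of ribosomal RNA, took 0.0799% to 0.226%, and box H/ACA snoRNAs, which guide pseudouridylation, took 0.194% to 0.349%.

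NOPCHAP1, the targeted gene, was still transcribed in the libraries labelled knockout. Its transcript, listed under the older symbol C12orf45 with gene number 121053 (GENCODE v29, GRCh38, chromosome 12, 104986310 to 105074197, plus strand), was at 56.9, 74.9 and 67.1 CPM (read counts scaled to library size) in KO 1, KO 2 and KO 3. The control libraries were at 79.9, 73.1 and 72.9 CPM. The means were 66.3 ± 9.02 CPM (SD, n = 3) and 75.3 ± 3.98 CPM (SD, n = 3). The log2 fold change of KO against control was -0.18 (SE 0.12), with an adjusted p of 0.910 in edgeR's quasi-likelihood test. The transcript level thus did not check the labels, and the labels do not say how the gene was disrupted.

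Few genes separated the clones. MFAP2, a protein of extracellular microfibrils, and PNPLA4, a lipid hydrolase, were nearly absent from the KO libraries. MFAP2 had 1, 0 and 0 reads in KO 1, KO 2 and KO 3 against 147, 133 and 53 in the controls, a ratio of pooled rates of 0.00316 (95% counting interval 7.99e-05 to 0.0178). PNPLA4 had 0, 0 and 1 reads against 38, 17 and 39, a ratio of 0.0112 (95% counting interval 0.000281 to 0.0640). Both passed edgeR's quasi-likelihood test, with adjusted p-values of 0.00922 and 0.0182. ESRP2, an epithelial splicing regulator, fell by 3.54 on the log2 scale (SE 0.38, edgeR adjusted p = 0.00922), and ANGPT1, a ligand of the TIE2 receptor, fell by 2.52 (SE 0.35, edgeR adjusted p = 0.0480).

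VAMP8, a SNARE of vesicle fusion, fell by 1.77 (SE 0.20, edgeR adjusted p = 0.0154), from 7.14 ± 1.27 CPM (SD, n = 3) in the controls to 2.13 ± 0.418 CPM (SD, n = 3). CA8, a carbonic anhydrase-related protein, fell by 1.27 (SE 0.13, edgeR adjusted p = 0.00922), and the tyrosine kinase SYK fell by 1.13 (SE 0.14, edgeR adjusted p = 0.0182). The zinc finger gene ZNF726 rose by 1.46 (SE 0.15, edgeR adjusted p = 0.00922), and THPO, which encodes thrombopoietin, rose by 2.56 (SE 0.35, edgeR adjusted p = 0.0407). For each of these 9 genes the values of the KO and control libraries did not overlap. In GENCODE v29 (GRCh38) the near-absent genes lie on chromosome 1 (MFAP2, 16974502 to 16980835) and chromosome X (PNPLA4, 7898247 to 7927739), and ESRP2, ZNF726 and THPO lie on chromosomes 16 (68229111 to 68238102), 19 (23914876 to 23945159) and 3 (184371935 to 184381968). VAMP8 lies on chromosome 2 (85561562 to 85582031), SYK on chromosome 9 (90801787 to 90898549), and CA8 and ANGPT1 on chromosome 8 (60187347 to 60281412 and 107249482 to 107498055). MFAP2, ESRP2, PNPLA4, THPO and ANGPT1 lie outside the naming rule, at a mean of under 2 CPM, and were named after their values were seen.

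These 9 genes, 2 higher and 7 lower, were all that passed an adjusted p of 0.05 among 14724 genes tested with edgeR. At an unadjusted p under 0.05 there were 846 genes, where 736 are expected if no gene differs. In a check chosen after seeing the data, other splits of the 6 libraries gave 61 to 2510 such genes. Splits with 846, 1225 and 1891 were among them, so this count did not set the clones apart. The KO and control groups did not overlap for 1813 genes, or 12.3%, where chance gives 10% for 3 against 3. DESeq2, run on 21105 genes with its own filter, called 38 genes, 6 higher and 32 lower. It called 40 on the 14724 genes, a setting chosen after seeing the data, and limma-voom called 7. The count was 0 without KO 3, 5 without KO 2, 5 without control 1 and 4 without control 2, it was 1 (MFAP2) with the replicate number as a block, and it was 32 without KO 1 and control 3 together, a setting chosen after seeing the data. THPO was not called in any of the 6 fits with 1 library left out, nor with limma-voom or the block. Of the 6 fits with 1 library left out, ANGPT1 was called only in that without control 3, and it was not called with limma-voom, upper-quartile factors, the stricter filter or the block. PNPLA4 was called only in that without control 2, and it was not called with the block or without KO 1 and control 3 together. The stricter low-count filter removed THPO and PNPLA4 before the test, so it could not call them. In the same 6 fits SYK was lost without KO 2, KO 3, control 1 or control 2, VAMP8 without KO 2, KO 3 or control 2, CA8 and ZNF726 without KO 3 or control 2, and MFAP2 and ESRP2 only without KO 3.

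**Figure D1:**
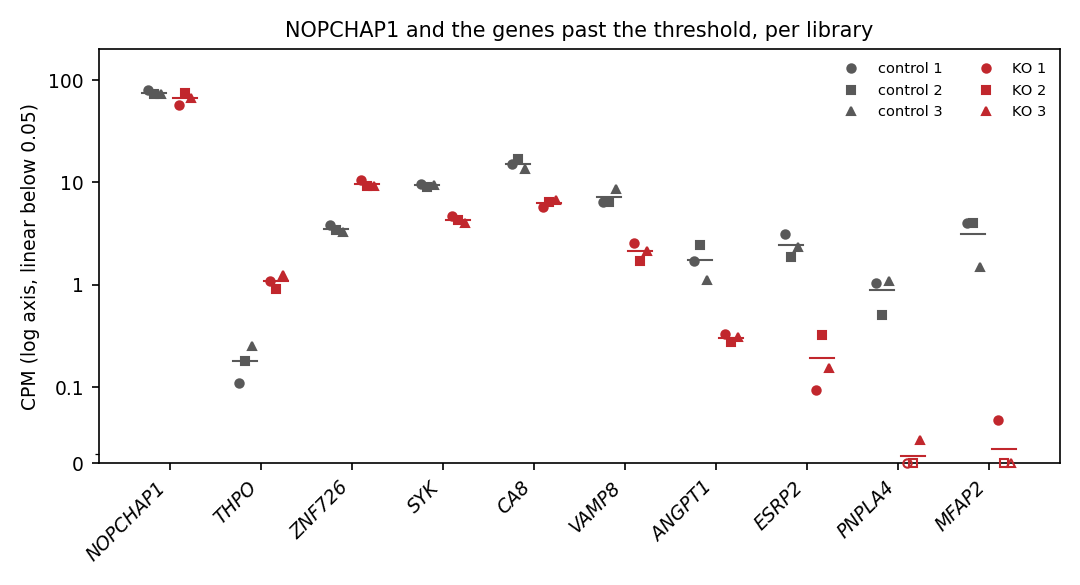
Each symbol is the CPM of 1 library on a log axis that is linear below 0.05, with controls in grey, KO libraries in red, the group mean as a bar and open symbols at 0. NOPCHAP1 overlaps between the groups, while the KO and control symbols stand apart for each of the 9 genes that passed the threshold.

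The next comparison asked whether the box C/D class as a whole was lower in the KO clone, as the series title ties NOPCHAP1 to the assembly of box C/D particles with NOP58. No single box C/D snoRNA passed the test: of 146 tested, 0 passed in edgeR and 1 had an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. In simulated counts a 1.5-fold fall of all box C/D snoRNAs gave 0 calls among 141, and a 2-fold fall 57 among 138, so single calls could not show a fall as small as 1.5-fold. The median log2 fold change was 0.055, with 88 snoRNAs higher and 58 lower. The mean log2-CPM per library was 0.12 higher in KO (exact two-sided permutation p = 0.8), with single KO and control libraries differing by -0.39 to 0.80. SNORD118, the U8 snoRNA gene, had 0 reads in every library. Total RNA holds pre-mRNA, and intron reads of a host gene can be counted on a snoRNA. These rows may therefore not measure mature snoRNAs alone. SNORD49A, at -0.58 (SE 0.25, edgeR adjusted p = 0.862), and SNORD45B, at 0.33, had the smallest p-values. With 1 library left out SNORD49A was between -0.84 (without KO 1) and -0.28 (without control 3). Among the box C/D snoRNAs with the most reads, SNORD133 was at -0.14, SNORD17 at -0.024, SNORD13 at 0.011, SNORD10 at 0.18 and SNORD15B at -0.027, none past the threshold.

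SNORD3A, the U3 snoRNA gene (GENCODE v29, GRCh38, chromosome 17, 19188016 to 19188714), did not follow the groups. It had 1, 45853 and 30454 reads in KO 1, KO 2 and KO 3, and 10, 9248 and 3 in control 1, control 2 and control 3. Its log2 fold change was 2.79 with an SE of 2.14 (edgeR adjusted p = 0.944). U3 has several near-identical gene copies, so the count of this row is uncertain.

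The box H/ACA snoRNAs, the class used here as the comparison, had no call gene by gene either. Of 106 tested, 0 passed in edgeR, 5 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. The median log2 fold change was 0.14, with 82 higher and 24 lower. SNORA77 was at 1.14 and SNORA72 at 0.59, and the abundant SNORA73A, SNORA73B and SNORA63 were at 0.17, 0.10 and 0.22. As a list, H/ACA snoRNAs stood above the other genes by camera with a preset correlation (adjusted p = 0.000167), and not with the correlation estimated (adjusted p = 0.931 with an estimated correlation). The C/D list did not pass (adjusted p = 0.0587, and adjusted p = 0.953 with an estimated correlation). The median fell below 0 without KO 1 (C/D -0.12, H/ACA -0.057) and without control 1 (C/D -0.11, H/ACA -0.070), and the C/D list passed camera without KO 2, without KO 3 or without control 3, with medians of 0.15, 0.18 and 0.29. Without control 1 it passed camera on the lower side (adjusted p = 0.00552). The C/D median was also below 0 in 2 corrected fits chosen after seeing the data, at -0.014 with a surrogate variable and -0.051 with a correction for GC content and transcript length.

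The difference between the classes was tested per library. The mean log2-CPM of C/D minus that of H/ACA snoRNAs was -0.90 ± 0.099 (SD, n = 3) in the KO libraries and -0.83 ± 0.059 (SD, n = 3) in the controls. The difference of -0.061 did not pass (exact two-sided permutation p = 0.4, where 0.1 is the smallest p that 3 against 3 allows), single KO and control libraries differed by -0.18 to 0.12, and leaving out 1 library gave -0.13 (without KO 3) to -0.027 (without KO 2). With a median over genes it was -0.098 (exact permutation p = 0.1). With summed counts in place of a mean over genes the difference was 0.40 (exact permutation p = 0.3). It was -0.19 when SNORD3A was left out of the sum (exact permutation p = 0.2). The mean over genes also includes SNORD3A. Without U3 rows the C/D mean was 1.165 in KO 2 (1.224 with them), 1.125 in KO 3 (1.175) and 1.238 in control 2 (1.279). It was higher without them in KO 1 (1.653), control 1 (0.835) and control 3 (1.599). The H/ACA means were 2.546, 2.193 and 1.958 in KO 1, KO 2 and KO 3. In control 1, control 2 and control 3 they were 1.628, 2.066 and 2.465. By these values the U3 rows made the difference between the groups smaller. The difference of means between the classes was not tested without U3 rows.

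**Figure D2:**
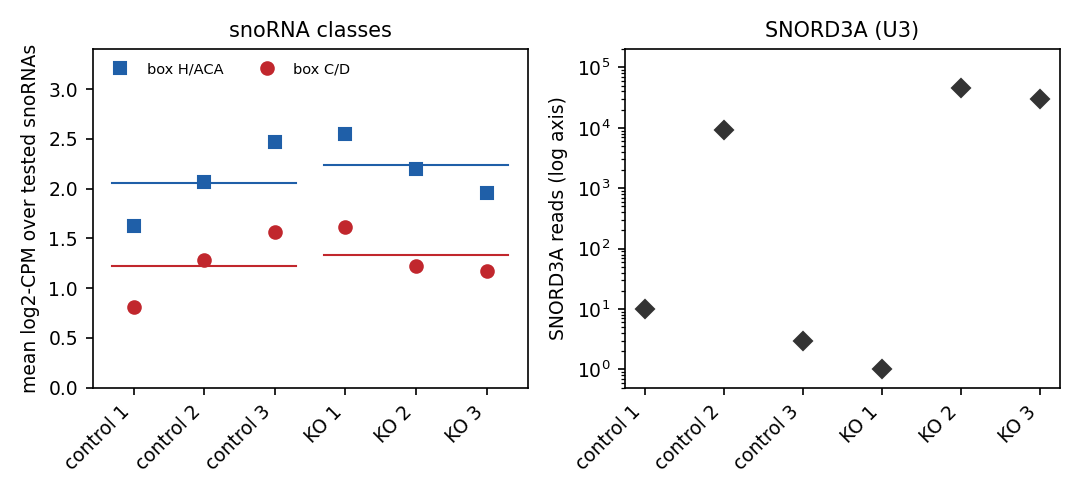
The left plot gives the mean log2-CPM over the tested snoRNAs of each class in each library, with lines at the group means, and the right plot gives the reads of SNORD3A on a log axis. Both classes were highest in KO 1 and control 3 and lowest in control 1, and SNORD3A reads were between 1 and 10 in KO 1, control 1 and control 3.

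The libraries differed in their reads on short transcripts, which the snoRNA levels followed only in part. KO 1 and control 3 held relatively more reads on short transcripts, with correlations across genes of transcript length and deviation from the mean of 6 libraries of -0.296 and -0.225 (Spearman), against 0.279 in KO 2, 0.0758 in KO 3, 0.233 in control 1 and -0.0101 in control 2. Both snoRNA classes were highest in KO 1 and control 3 and lowest in control 1, but KO 2 was above KO 3 in both. The leading principal component held 40.5% of the variance and set KO 1 (-34.9) and control 3 (-14.9) against control 1 (29.6), not KO against control. The second held 23.5% and set KO 2 (-22.1) and KO 3 (-19.7) apart from the controls (3.64 to 18.6), with KO 1 (7.71) among the controls. The log2 fold changes of KO against control had a Spearman correlation of -0.251 with GC content and -0.0346 with transcript length, across genes.

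The proteins of the box C/D particle and its assembly showed no change that passed the test. Of the 4 core proteins, NOP58 was at 0.14 (SE 0.11), NOP56 at 0.025, the methyltransferase FBL at -0.25 (SE 0.17) and SNU13 at -0.033. The FBL estimate rested on control 3 and was -0.0056 without it. Of 25 tested assembly and PAQosome genes, 0 passed in edgeR over all genes or adjusted over the list alone, and 1, ECD at 0.26 (SE 0.099), had an unadjusted p under 0.05. DESeq2 and limma-voom called 0 in both groups. The ATPases RUVBL1 and RUVBL2 were at 0.16 and -0.096, and the assembly factors NUFIP1, ZNHIT3, ZNHIT6 and NOLC1 at 0.18, 0.052, 0.064 and 0.15. In the R2TP and prefoldin-like parts, RPAP3 was at 0.17, PIH1D1 at -0.14, URI1 at 0.15, UXT at -0.066, PFDN2 at -0.013, PFDN6 at 0.014, PDRG1 at -0.062, POLR2E at -0.076 and WDR92 at 0.068. HSP90AA1, HSP90AB1, ZNHIT2, TTI1, TTI2, TELO2, AAR2, TAF9 and TGS1 were between -0.12 and 0.24. The medians were -0.0042 for the core list and 0.064 for the assembly list. The sign of SNU13, NOP56, RUVBL2 and several others near 0 turned with the processing.

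Genes of ribosome assembly stood higher in the KO libraries as lists, without any single member passing. In the list of the small-subunit processome and 40S assembly, 38 of 41 genes had a higher estimate, with a median log2 fold change of 0.17. The leading members were DDX52 at 0.39 (SE 0.11) and UTP15 at 0.35 (SE 0.12). In the 60S assembly list, 36 of 40 genes had a higher estimate, with a median of 0.13, and NOC3L at 0.31 and MAK16 at 0.31 had the smallest p-values. Both lists passed camera with the preset correlation (adjusted p = 1.62e-11 and 7.56e-08), and neither passed with an estimated one (adjusted p = 0.722 with an estimated correlation for both). The mean log2-CPM of the 40S list was 6.06 ± 0.040 (SD, n = 3) in KO and 5.88 ± 0.19 (SD, n = 3) in control libraries (exact two-sided permutation p = 0.3), and the 60S list gave the same p. Over the 81 genes of both lists, control 3 (0.129 relative to the mean of the 6 libraries) lay within the KO range of 0.0208 to 0.146.

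Another 4 lists stood higher. The Pol I and nucleolus list had a median of 0.068, with RRN3, a Pol I initiation factor, at 0.29 and TAF1D at 0.21 (camera adjusted p = 0.0419, and adjusted p = 0.931 with an estimated correlation). Mitochondrial ribosomal proteins had a median of 0.038, with MRPS30 at 0.17 and MRPL1 at 0.21 (camera adjusted p = 0.0315, and adjusted p = 0.953 with an estimated correlation). Spliceosomal snRNAs had a median of 0.17, with RNU5E-1 at 0.52 and RNU4-2 at 0.79 (camera adjusted p = 0.0174, and adjusted p = 0.931 with an estimated correlation). The endoplasmic reticulum unfolded protein list had a median of 0.053, with SEL1L at 0.28 and DNAJB9 at 0.26 (camera adjusted p = 0.0174, and adjusted p = 0.722 with an estimated correlation). Mean log2-CPM per library overlapped between the groups for all 4 (exact permutation p = 0.3 to 0.8). All 4 calls were lost without KO 1 and without control 1, those of Pol I and of the unfolded protein list also without control 2, and each in the fit with a surrogate variable, chosen after seeing the data. The mitochondrial ribosomal and Pol I calls were also lost with a stricter low-count filter, and the mitochondrial ribosomal call with upper-quartile factors and with the GC and length correction, the latter chosen after seeing the data.

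Matrix, neuronal and WNT genes stood lower. In the extracellular matrix and adhesion list, 21 of 26 genes had a lower estimate, with a median of -0.24, FBN1 (fibrillin) at -0.57 (SE 0.14) and LOX (a collagen crosslinking enzyme) at -1.16 (SE 0.36). In the neuronal and neural crest list, 12 of 15 were lower, with a median of -0.29, the GDNF receptor gene GFRA1 at -1.09 and the neurofilament gene NEFL at -0.54. In the WNT list, 16 of 17 were lower, with a median of -0.17, RNF43 at -1.07 and WNT5B at -0.92. RNF43, which lowers WNT receptor levels, was the 1 member to pass when adjusted over the list alone. Over all genes it did not pass (edgeR adjusted p = 0.491). The camera adjusted p-values were 0.00174, 0.00227 and 0.00813, and none passed with an estimated correlation (adjusted p = 0.931, 0.722 and 0.722 with an estimated correlation). Mean log2-CPM per library overlapped between the groups for the matrix list (exact permutation p = 0.4, single KO and control libraries differing by -0.80 to 0.15) and not for the neuronal and WNT lists (exact permutation p = 0.1 for both, unadjusted and the smallest possible). The closest KO and control libraries differed by only -0.0043 in the neuronal list and -0.0063 in the WNT list. All 3 calls were lost without control 1, and those of the matrix and WNT lists also without KO 1. Neither marker list of another cell type that could be tested passed, though 4 of 4 tested colorectal epithelial markers had a lower estimate (median -0.31, KRT8 -0.38, EPCAM -0.43, camera adjusted p = 0.0587, and exact permutation p = 0.1 for the mean per library, which did not overlap) and 6 of 7 fibroblast markers (median -0.28, COL3A1 -0.93, PRRX1 -0.60, camera adjusted p = 0.143), of which COL1A1 and COL3A1 are also in the matrix list. Of the 2 tested haematopoietic markers 1 was lower.

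The ATF4 target and cholesterol synthesis lists also stood lower. In the ATF4 list, 18 of 23 genes had a lower estimate, with a median of -0.10, the serine synthesis enzyme PHGDH at -0.41 (SE 0.11) and TRIB3 at -0.39 (SE 0.12) (camera adjusted p = 0.00813, and adjusted p = 0.722 with an estimated correlation). In the cholesterol synthesis list, 19 of 23 were lower, with a median of -0.082, TM7SF2 at -0.65 and SREBF2 at -0.31 (camera adjusted p = 0.0394, and adjusted p = 0.722 with an estimated correlation). For both lists the mean log2-CPM per library did not overlap between the groups (exact permutation p = 0.1, unadjusted and the smallest possible). The neuronal, WNT and colorectal epithelial lists did not overlap either, and chance gives this for 10% of lists at 3 against 3. The cholesterol call was lost with RLE size factors and without KO 2, KO 3, control 2 or control 3.

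Of 39 lists with at least 3 tested members, 12 passed camera with a preset correlation, 7 higher and 5 lower, 0 passed with an estimated correlation and 0 passed fry. In a check chosen after seeing the data, 6 of the 10 splits of the libraries, the real one included, called as many lists. Another split called 24, so this count did not set the clones apart. The 5 lower lists were not compared with other splits one by one. No member of the 12 lists passed the edgeR threshold over all genes. The count of lists was 7 without KO 1 and 19 without control 3.

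**Figure D3:**
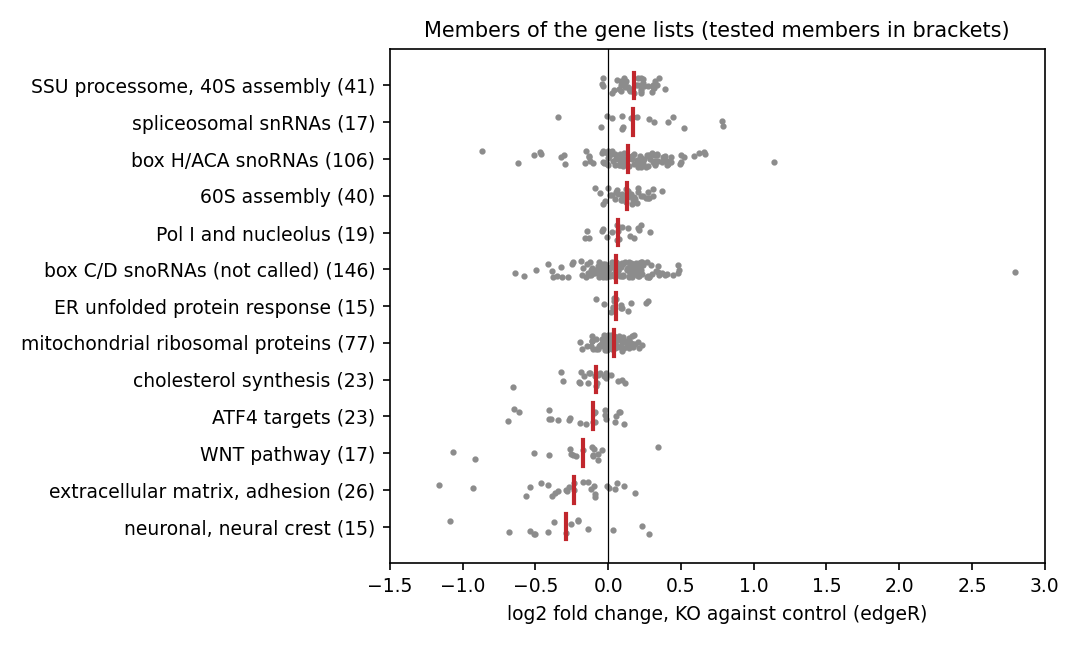
Each point is the edgeR log2 fold change of 1 tested gene in the 12 lists that passed camera and in the box C/D snoRNA list, and red bars are list medians, from 0.17 in the 40S assembly list to -0.29 in the neuronal list. The point at 2.79 is SNORD3A.

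The other lists did not pass camera. Adjusted over the list alone, SNAI2 (0.38) and ID2 (0.39) rose in the EMT and TGF-beta list (median 0.091), ENO2 (-0.82) fell in the hypoxia and glycolysis list (median -0.050, SLC2A3 0.66), GATA3 (-0.94) fell in the kidney and adrenal list (median 0.016), and RNF43 fell in the list of H/ACA host genes (median 0.058, KPNA4 0.32). Over all genes none of SNAI2, ID2, ENO2, GATA3 and RNF43 passed (edgeR adjusted p = 0.534, 0.569, 0.309, 0.491 and 0.491). The adjustment over the list alone does not account for the number of lists. ZNF726 was the 1 gene to rise among 434 ZNF-numbered genes, over all genes and adjusted over the list alone (median 0.013). Targets of p53 had a median of -0.066 (PHLDA3 -0.46, BAX -0.23), cytosolic chaperones 0.10 (HSPA1B -0.29, HSPB1 -0.37), interferon response genes 0.0083 (OAS3 0.98, ISG15 -0.63), and immediate early genes -0.087 (IER2 -0.44, DUSP4 -0.45). Cytosolic ribosomal proteins had a median of -0.047 (RPL3 -0.28, RPL13A -0.28) and nuclear genes of oxidative phosphorylation -0.0051 (NDUFA7 -0.37, NDUFA3 -0.33). Genes of replication had a median of 0.013 (CDC6 0.18, TIPIN 0.17), of mitosis 0.043 (CCNA2 0.34, HMMR -0.23), and replication-dependent histones 0.019 (H3C6 0.30, H2BC8 0.33).

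In the lists closest to PAQosome clients, the PI3K-like kinases had a median of 0.043 (SMG1 0.16, TRRAP -0.15), the U4 and U5 snRNP proteins 0.023 (SNRNP200 -0.25, PPIH 0.14), and the H/ACA core and assembly proteins 0.025 (SHQ1 0.18, NAF1 0.15). The scaRNAs had a median of 0.0070 (SCARNA14 0.81, SCARNA9L -0.64), other small RNAs 0.25 (VTRNA1-1 0.47, VTRNA1-2 0.46), and C/D host genes -0.038 (WDR43 0.27, TAF1D 0.21). HOX genes had a median of -0.020 (HOXC6 -0.40, HOXC13 -0.34) and clustered protocadherins -0.011 (PCDHGA11 -0.47, PCDHB15 0.44). The squamous list had 2 tested genes (CAV1 at -0.48) and the haematopoietic list 2 (CORO1A at -0.16), too few for a test. Median, mean and camera direction differed in sign for the core C/D proteins, both host gene lists, the HOX, interferon and kidney lists, none of which passed.

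The change of a snoRNA was compared with that of the gene whose intron or transcript holds it. Across 201 snoRNAs with a tested host gene, the log2 fold changes had a Spearman correlation of 0.132 (permutation p = 0.064) and a Pearson correlation of 0.148 (permutation p = 0.034). The Spearman correlation was 0.150 for box C/D and 0.104 for box H/ACA snoRNAs, and the adjusted permutation p-values of the 3 Spearman correlations were 0.18, 0.18 and 0.32. These are correlations across genes, which are not independent replicates. Without control 3 the Spearman correlation was 0.0336.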

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

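The alternatives with 1 surrogate variable, with the GC and length correction, without the pair KO 1 and control 3, with summed counts without SNORD3A, and with DESeq2 on the genes of the edgeR filter were chosen after seeing the data. The cause of the changes below was not tested unless stated. The 9 genes past the threshold became 38 with DESeq2, run on 21105 genes with its own filter, 40 with DESeq2 on the 14724 genes of the edgeR filter, 22 without a low-count filter, 28 with 1 surrogate variable and 15 with the GC and length correction, and these 5 sets held all 9. There were 32 without the pair KO 1 and control 3, holding 8 of the 9. The count was 4 at an adjusted p under 0.01 and 1 with glmTreat, both stricter by construction. It was 7 with limma-voom, 8 with upper-quartile factors and 9 with RLE factors or without small RNAs in the library sizes. With the stricter filter, which left THPO and PNPLA4 untested, it was 6. Leaving out 1 library gave 0 (without KO 3) to 13 (without control 3), and THPO was lost in all 6 of these, ANGPT1 and PNPLA4 in 5 each, SYK in 4 and VAMP8 in 3. Same-numbered libraries deviated from their group means in opposite directions (correlations -0.408, -0.088 and -0.215), and no library correlated best with its own number. These values gave no sign that the numbers pair the samples. Beside the library-wide trends they cannot exclude a smaller effect shared by same-numbered libraries. With the replicate number as a block, 1 gene, MFAP2, was called, and the box C/D median was 0.068, past the camera threshold (adjusted p = 0.0442).

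The box C/D list, short of the camera threshold at a median of 0.055, passed with upper-quartile factors (0.032) and without the pair KO 1 and control 3 (0.11). It also passed as higher without KO 2, KO 3 or control 3, and as lower without control 1 (-0.11, camera adjusted p = 0.00552). Its median was -0.014 with 1 surrogate variable and -0.051 with the GC and length correction, and -0.12 to 0.29 with 1 library left out. The H/ACA median was -0.070 to 0.40 with 1 library left out and above 0 in the other alternatives. The C/D minus H/ACA difference of -0.061 turned to 0.40 with summed counts, was -0.098 with a median over genes (exact permutation p = 0.1) and -0.13 to -0.027 with 1 library left out. The 12 lists became 7 to 19 with 1 library left out, without KO 1 and without control 3, and 10 to 17 in the other alternatives. The 40S, 60S and ATF4 lists passed camera in all 17 alternatives. The cholesterol call was lost in 6 of them, among them RLE factors and the replicate block. NOPCHAP1 stayed short of the threshold in all 17, from -0.28 to -0.079, and the correlation with host genes was 0.0336 to 0.162.

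Among 2126 single-gene values there were 77 changes of sign, in 28 genes, all of them past the threshold in neither fit, and the 28 genes were at most 0.24 in absolute log2 fold change in the reported edgeR test. With the GC and length correction, RUVBL2 was 0.011, POLR2E 0.030, SNU13 0.015, PFDN2 0.032 and SNORD13 -0.079. Without the pair KO 1 and control 3, RUVBL2 was 0.016, TTI2 0.0034, POLR2E 0.076, PDRG1 0.15, SNU13 0.0053, PFDN2 0.072, PFDN6 -0.068, TRRAP 0.074, SNORD17 0.030, SNORD13 -0.088 and SNORD15B 0.17. With upper-quartile factors, NOP56 was -0.0026, PFDN6 -0.012 and SNORD13 -0.011. With 1 surrogate variable they were -0.029, -0.12 and -0.15. PFDN2 was 0.0044 with DESeq2 and 0.00051 with RLE factors. PFDN6 and SNORD15B were -0.014 and 0.034 with limma-voom, and -0.0086 and 0.030 with the block. With 1 library left out, the ranges were HSP90AB1 -0.015 to 0.31, ZNHIT2 -0.053 to 0.48, TTI2 -0.20 to 0.064, WDR92 -0.026 to 0.14, UXT -0.15 to 0.032, HSP90AA1 -0.042 to 0.28, POLR2E -0.24 to 0.069, ZNHIT3 -0.039 to 0.12, TTI1 -0.10 to 0.018, AAR2 -0.075 to 0.30, PDRG1 -0.21 to 0.20, SNU13 -0.11 to 0.074, TELO2 -0.15 to 0.28, NOP56 -0.071 to 0.11, PFDN2 -0.11 to 0.16, PFDN6 -0.27 to 0.21, TRRAP -0.33 to 0.030, PPIH -0.023 to 0.28, CORO1A -0.33 to 0.043, SNORD133 -0.73 to 0.22, SNORD17 -0.16 to 0.14, SNORD13 -0.36 to 0.28, SNORD10 -0.031 to 0.47, SNORD15B -0.27 to 0.25, SNORA73A -0.018 to 0.54, SNORA73B -0.10 to 0.41 and SNORA63 -0.083 to 0.65. Depth limits MFAP2, PNPLA4 and THPO most, each with under 20 reads in all libraries of 1 group together.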

Other observations

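The tests of GC content and length, of U3 rows, of small RNA recovery and of counting rules were chosen after the results were seen. So were those of other splits into groups and of the neighbours of SYK. The tests of neighbouring genes and of the assembly lists in other splits were chosen before their own values were seen. They too were chosen after the calls that they concern were known. DESeq2 and the fit with 1 surrogate variable, the latter chosen after seeing the data, shared 25 calls, and these included all 9 genes of the edgeR test. Genes picked from the others after their values were seen were the receptor tyrosine kinase ERBB4 (-2.38 with DESeq2 and -2.30 with the surrogate variable), the collagen COL2A1 (-1.21 and -1.16), the junction protein F11R (-0.90 and -0.96), the axonal motor KIF1A (-0.65 and -0.66), the synaptic vesicle protein SV2A (-0.62 and -0.67) and the pentraxin NPTX1 (-0.83 and -0.80). The cancer-testis antigen MAGEC2 (1.91 and 1.86) and the annexin ANXA1 (1.35 and 1.31) were higher. The surrogate variable fit also called 1 box C/D snoRNA, SNORD49A, at -0.70 (edgeR adjusted p = 0.0330), which was short of the threshold in the other alternatives, from 0.115 to 1 in adjusted p.

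The 9 genes that passed the threshold kept their calls, 9 of 9, after the trend of each library on GC content and length was removed, which argues against length and GC differences between libraries as the whole cause. Loss of a chromosome segment around the genes that fell was tested with 92 tested genes within 1 Mb. Their median log2 fold change was -0.031 (95% bootstrap interval -0.072 to 0.021), which argues against loss of a wide segment as the general cause, though 82 of them lie near MFAP2, VAMP8 and ESRP2, and loss or silencing of a single gene remains open. The interval resampled genes as if independent and does not measure the spread between libraries. Loss of a chromosome segment around SYK stays open too, since its 4 tested neighbours had a median of -0.494 and ranged from -0.98 to 0.12. Of the 10 splits of the 6 libraries, 2 gave 9 or more genes, the real one with 9 and another with 12, and 10 splits are too few for a share under 0.05; a difference between 2 clones that is not due to NOPCHAP1 cannot be told apart from an effect of the knockout, since the labels name 1 clone per group.

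SNORD3A reads were near 0 in KO 1, control 1 and control 3 and at 45853, 30454 and 9248 in KO 2, KO 3 and control 2. Transfer of its reads to another U3 row is argued against by the 11 other SNORD3 rows, which held at most 72 reads together in any library. Pseudogene rows were left out of that sum. Poor recovery of small RNAs in KO 1 and control 3 is argued against as well, because their levels of the other box C/D snoRNAs lay at least 0.36 (log2) above those of KO 2, KO 3 and control 2, but for control 1, whose level was lowest by -0.29, it stays open. A counting rule for repeated sequences that differed between whole libraries could have given other rows the same presence and absence, and 0 other rows had it at 10-fold. The check scored only rows above a minimum read count and missed smaller shifts, so it cannot exclude such a rule. What set the SNORD3A count stays open, and no biological explanation was tested, since the split does not follow the groups.

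The higher estimates of the 40S and 60S assembly lists, 81 genes together, may reflect variation of these lists among libraries within a group. Of the splits of the 6 libraries, 2 others reached medians of 0.180 and 0.236 for these genes, against 0.149 for the real split, and per library the mean relative to all 6 was 0.146, 0.0208 and 0.0787 in KO 1, KO 2 and KO 3 and -0.241, -0.134 and 0.129 in control 1, control 2 and control 3. Length and GC differences are argued against as the whole cause, since the median relative to all genes was 0.159 before and 0.148 after the trend was removed (95% bootstrap interval 0.13 to 0.188). That interval resampled genes and does not measure the spread between libraries. The real split called 12 lists and 6 of 10 splits called as many, up to 24, and 10 splits are too few for a share under 0.05. A clone or knockout effect stays open and untested beside the variation among libraries.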
